A study of Mus musculus with 15 samples.

How the data were processed

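Total RNA of mouse embryonic stem cells was sequenced on an Illumina HiSeq X instrument in 15 samples, which per the labels fall into 5 groups of 3 replicates. The groups were a mock control, oligomycin at 1 nM or 10 nM, and 2-deoxy-D-glucose (2-DG) at 5 mM or 10 mM, each inhibitor for 48 hours. The time for which the mock samples were kept is not given in the labels, and the labels do not say whether the 3 replicates of a group were separate cultures. The growth medium per the labels was a serum medium with leukemia inhibitory factor, and no feeder layer is named.

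The values deposited by the authors are FPKM (fragments per kilobase scaled to the mapped reads), 1 value per gene and sample. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3 and HTSeq 0.6.0 and the build GRCm38, without a role for each tool. Raw counts were not used here. The table held 32152 genes with a symbol and an Ensembl identifier, and no gene was 0 in all samples. Another 1 line held no gene and was left out. Spreadsheet software had turned 26 symbols into dates, and all 26 were restored from the identifiers. Genes were kept apart by identifier, since 37 of them shared a symbol with another. Of the identifiers, 32077 were in the mouse annotation used here (GENCODE M21), and 29920 (93.1%) had the same start and end there. Coordinates are 1-based on GRCm38, as in the table.

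Sequencing depth was worked out from the values themselves. Low values of a gene step in whole multiples of what 1 read is worth, and 95.4% to 96.1% of the values up to 20 reads lay within 0.05 of a whole number of reads, where chance gives 10%. Depths relative to the first control sample came from 13093 genes with values under 0.3 FPKM in all samples. With exon lengths from the annotation, the steps gave 17.4 to 19.2 M reads (M, mega) per sample. Of the 3759 genes used for this estimate, 92.3% lay within 1% of it. The share of whole numbers above was worked out with these exon lengths and depths. In the first control sample, 1 read in a gene of 1 kilobase was worth 0.0542 FPKM. These depths set the counting error, but no interval per gene is given, since the spread between replicates was measured directly.

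Genes with at least 1 FPKM in at least 3 samples were tested, 13284 in all, of which 11808 were protein coding, and 18868 genes were left out. Values were analysed as log2(FPKM + 1), which understates the change of genes with low values. A linear model with 1 mean per group was fitted to all 15 samples with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a trend). Its two-sided moderated test was used for 7 comparisons, with Benjamini-Hochberg adjustment over the genes tested in each comparison and a threshold of 0.05. Errors of log2 changes are standard errors from this model, and errors of FPKM values are standard deviations over 3 replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading and plotting.

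Before the data were examined, 26 gene lists, the comparisons, the tests, the alternatives and the rule for named genes were fixed. The lists covered cell states (naive pluripotency, formative and primed epiblast, primitive endoderm, mesoderm and primitive streak, neuroectoderm, trophectoderm, germline genes, 2-cell-like genes), fibroblast feeder markers, energy metabolism (glycolysis, TCA cycle and pyruvate dehydrogenase, respiratory complexes I to IV, ATP synthase, mitochondrially encoded mRNAs), stress responses (ATF4 and integrated stress response, endoplasmic reticulum unfolded protein response, mitochondrial chaperones and proteases, HIF and hypoxia, p53, NRF2) and other processes (cell cycle, cholesterol synthesis and SREBP2 targets, hexosamine and N-glycan precursor synthesis, DNA methylation and demethylation enzymes, autophagy and lysosome, cytosolic ribosomal proteins). The 25 lists with at least 5 tested members were tested with camera, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over the lists of a comparison. The 2-cell-like genes lay under the filter and are given as a summed FPKM. Another 4 lists (genes restricted to stem cells, epithelial genes of stem cells, macrophage genes and interferon response genes) were written after the data had been seen and were not tested with camera.

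The named genes of each comparison with control are the 10 largest rises and the 10 largest falls in log2 value among genes past the threshold with a mean of at least 5 FPKM in a compared group and all 3 treated samples outside the range of the controls. Predicted genes, ribosomal and small nuclear or nucleolar RNA genes and pseudogenes were left out. The other 3 comparisons took the first 5 each way, and up to 4 members of each list with the largest changes past the threshold were added. Pou5f1, Sox2, Nanog, Zfp42, Hk2, Slc2a1, Ldha, Hspa5, Ddit3, Trib3 and Cdkn1a were named whatever their values. Any other gene named was chosen after its values were seen, and this is said beside it.

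The procedure was tested on simulated data made from the spread between the replicates, with 200 changed genes among 13284. Of changes of 1 on the log2 scale, 94% to 99% were recovered, and of changes of 0.3, 28% to 42%. The share of false calls was 0.8% to 6.7% over the 7 comparisons, and 0 of 100 random gene lists were called in each. The simulated genes varied independently of one another, so the list count says nothing about lists whose genes vary together. Alternatives tried were a pseudocount of 0.1, a filter at 5 FPKM, no filter, median ratio scaling, quantile normalization, a fit of only the groups compared, the replicate number as a block, and leaving out each sample in turn. The samples of each comparison were also split in all 10 ways into 3 against 3.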

Results

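The transcriptomes of mouse embryonic stem cells, pluripotent cells grown from the early embryo, were measured by RNA sequencing in 5 groups of 3 samples. The cells were treated for 48 hours with oligomycin, which blocks the mitochondrial ATP synthase, at 1 nM or 10 nM, or with 2-deoxy-D-glucose (2-DG), a glucose analog that blocks glycolysis, at 5 mM or 10 mM. Mock-treated cells were the control, and the labels call the treatments low and high inhibition of oxidative phosphorylation and of glycolysis. Expression is given as FPKM, and changes are log2 changes of FPKM + 1. Depth worked out from the value steps was 17.4 to 18.5 M reads (M, mega) in the controls, at least 18.3 M with 1 nM oligomycin, 18.6 to 18.7 M with 10 nM, 17.8 to 18.7 M with 5 mM 2-DG and up to 19.2 M with 10 mM. Between 12116 and 12499 genes per sample had at least 1 FPKM. The summed FPKM was 285204 to 325805, of which a single transcript, Gm23935, took 2.28% to 4.92%. Adjusted p-values measure only the spread between these samples, since the labels do not say that replicates were separate cultures.

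The first principal component, with 66.3% of the variance, set both oligomycin groups apart from the others in order of dose. The second, with 14.7%, set the controls apart from the 2-DG groups. Pearson correlations across genes were 0.9848 to 0.994 between samples of a group and 0.9025 to 0.991 between groups. Replicate 1 of 10 nM oligomycin stood farthest from its group (root mean square deviation 0.181), and its deviations rose with gene length (Spearman's rho 0.52 across 13275 genes, which are not independent replicates). The other two replicates of that group had rho of -0.46 and -0.38, and other groups also varied with length, with 0.36, 0.05 and -0.35 in the controls and -0.31 in replicate 1 of 1 nM.

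**Figure D1:**
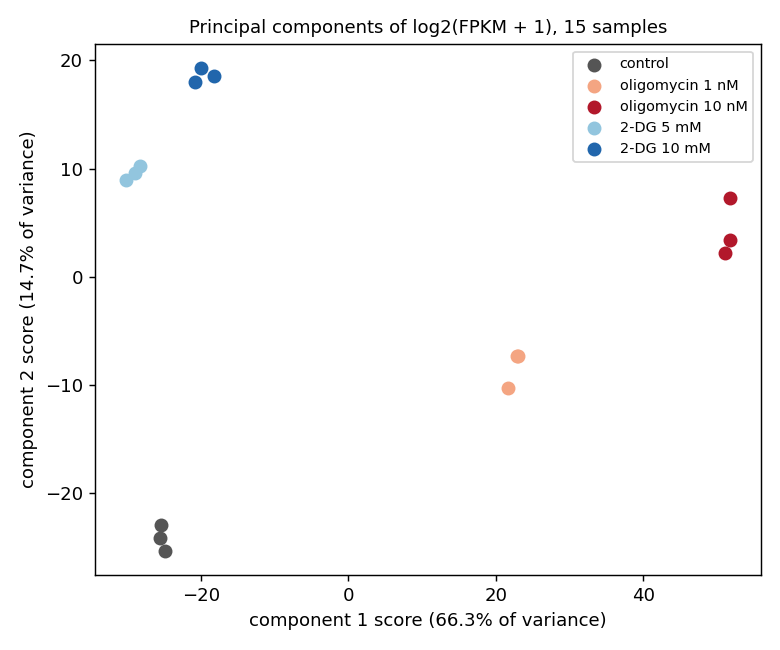
Scores of the 15 samples on the first and second principal components of log2(FPKM + 1), with the share of variance of each on the axis label and 1 point per sample. The oligomycin groups lie at 21.68 to 51.77 on the first component, and all other samples lie below 0.

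With oligomycin at 1 nM the core pluripotency factors stood lower, and stress and fibroblast genes higher, than in the controls. Pou5f1 (Oct4, ENSMUSG00000024406, chromosome 17, 35506018 to 35510772) fell from 122 ± 11.6 to 66.5 ± 1.14 FPKM (SD, n = 3), and Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633) from 196 ± 5.04 to 120 ± 3.1 FPKM. Ddit3 (ENSMUSG00000025408, chromosome 10, 127290774 to 127296288), which encodes the stress transcription factor CHOP, rose from 9.16 ± 0.066 to 39.7 ± 1.83 FPKM. Tgfb3, a growth factor of the TGF-beta family, rose from 12.2 ± 0.776 to 54.5 ± 1.73 FPKM. In total 8366 of 13284 genes passed the test, 3958 higher and 4408 lower, of which 210 rose and 224 fell at least 2-fold.

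Of the 24 naive pluripotency genes, 20 fell and 1 rose at 1 nM, with Dppa3 at -1.18 ± 0.14 (SE), Prdm14 at -1.16 ± 0.08 and Sox2 at -0.68 ± 0.09. The list passed the test as lower (adjusted p = 2.9e-06), but adjusted p = 0.092 with an estimated correlation. Formative and primed epiblast genes, active on the way out of the naive state, also fell, 16 of 18 (adjusted p = 1.9e-08), among them Zic2 at -2.1 ± 0.09 and the DNA methyltransferase Dnmt3b at -1.82 ± 0.05. Fibroblast feeder markers rose in 19 of 21 members (adjusted p = 3.6e-09), with a median of 0.86, led by the smooth muscle actin Acta2 at 1.6 ± 0.05 and the collagen cross-linking enzyme Lox at 1.4 ± 0.09. Those markers were abundant in the controls, Acta2 at 577 ± 10.3 FPKM. Primitive endoderm genes rose in 11 of 18 members with 0 lower (adjusted p = 2e-04), and the strongest were the basement membrane genes Col4a2 at 1.2 ± 0.08 and Col4a1 at 1.17 ± 0.08, which fibroblasts also express. Adjusted over the list alone, these 4 lists gave the same counts.

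ATF4 and integrated stress response genes rose in 34 of 39 members and fell in 1 at 1 nM (adjusted p = 7.7e-12), led by Ddit3 at 2 ± 0.07, the pseudokinase gene Trib3 at 1.85 ± 0.06 and the secreted stress factor Gdf15 at 1.67 ± 0.1. Autophagy and lysosome genes rose in 19 of 27 and fell in 4 (20 and 4 adjusted over the list alone, adjusted p = 4.9e-06), with the cargo receptor Sqstm1 at 1.05 ± 0.06, but with adjusted p = 0.079 with an estimated correlation. Of the 21 p53 response genes 14 rose and 2 fell (adjusted p = 7.3e-04), with the cell cycle inhibitor Cdkn1a at 0.87 ± 0.06, and adjusted p = 0.14 with an estimated correlation. Cell cycle genes fell in 29 of 30 members and rose in 1 (adjusted p = 8.9e-12), with cyclin E gene Ccne1 at -1.29 ± 0.06. Cholesterol synthesis and SREBP2 target genes fell in 23 of 24 members (24 adjusted over the list alone, adjusted p = 1.2e-09), with the isomerase Idi1 at -1.66 ± 0.1 and the synthase Hmgcs1 at -1.38 ± 0.06. Of 16 DNA methylation and demethylation enzymes 10 fell and 2 rose (adjusted p = 0.0037, and adjusted p = 0.079 with an estimated correlation). The ATF4, p53, cell cycle and DNA methylation counts were the same adjusted over the list alone, and fibroblast markers rose in the same samples (19 of 21 members).

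Of 18 nuclear genes of the ATP synthase, the target of the drug, 11 fell and 0 rose at 1 nM, also adjusted over the list alone, with Atp5g1 at -0.75 ± 0.12 (adjusted p = 0.019, and adjusted p = 0.71 with an estimated correlation). That call was lost without control replicate 3 (median -0.27, adjusted p = 0.055, within a range of 0.0084 to 0.71 over 9 alternatives). The genes of respiratory complexes I to IV fell in 15 of 61 members (13 adjusted over the list alone) and did not pass as a list (adjusted p = 0.092, 0.019 without control replicate 1, 0.82 with an estimated correlation, the ends of its range over 9 alternatives). Glycolysis genes were divided, with 5 of 23 higher and 13 lower, also adjusted over the list alone, and the list was not called (adjusted p = 0.14). The neuronal enolase Eno2 rose by 1.35 ± 0.06, while Ldha (lactate dehydrogenase A) changed by -0.55 ± 0.06, the glucose transporter Slc2a1 by -0.32 ± 0.05 and hexokinase Hk2 by -0.44 ± 0.06.

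The remaining 12 lists were not called at 1 nM, with 9 higher and 5 lower among 20 HIF and hypoxia genes, 11 and 5 among 28 unfolded protein response genes, and 0 and 11 among 75 cytosolic ribosomal protein genes. Adjusted over the list alone these were 9 and 6, 11 and 5, and 0 and 7. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 213 ± 6.36 in the controls and 214 ± 14.5 FPKM at 1 nM (adjusted p = 0.98). Counts higher and lower were 1 and 2 of 9 mesoderm and primitive streak genes, 5 and 6 of 13 neuroectoderm genes, 6 and 3 of 14 trophectoderm genes, and 2 and 3 of 14 germline genes. They were 3 and 8 of 24 TCA cycle and pyruvate dehydrogenase genes, 3 and 4 of 12 mitochondrially encoded mRNAs, 3 and 7 of 16 mitochondrial chaperones and proteases, 9 and 10 of 24 NRF2 genes, and 8 and 5 of 33 hexosamine and N-glycan precursor genes. These 9 pairs of counts were the same adjusted over the list alone. The neuroectoderm median was 0.08 and its mean -0.25, with the test pointing lower, and the TCA cycle median was 0.01 and its mean -0.01.

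With oligomycin at 10 nM the pluripotency factors stood lower and fibroblast genes higher than in the controls. A larger share of fibroblasts as part of the cause cannot be told apart from changes within the cells. Pou5f1 was at 30.2 ± 4.87 FPKM (SD, n = 3), 0.247 times the control mean, Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461) at 44.7 ± 5.8 against 171 ± 8.29, and Nanog at 56.1 ± 7.29 FPKM. Trh, which encodes thyrotropin-releasing hormone, fell from 191 ± 17.1 to 14.3 ± 2.08 FPKM, and Dnmt3b (ENSMUSG00000027478, chromosome 2, 153649450 to 153687730) from 92.7 ± 0.555 to 12.2 ± 0.688 FPKM. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255336) rose to 2370 ± 126 FPKM, 4.1 times the control mean, and the vasodilator peptide gene Adm rose from 8.7 ± 0.979 to 42.7 ± 5.87 FPKM. In total 10067 genes passed the test, 4523 higher and 5544 lower, and 813 rose and 1200 fell at least 2-fold. Without replicate 1 of this group, which stood apart, 10049 genes passed.

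Of the 24 naive pluripotency genes 23 fell at 10 nM, with a median of -1.79 (adjusted p = 3.9e-09). Dppa3 was at -2.86 ± 0.14, Dppa5a at -2.1 ± 0.12, Gdf3 at -2.1 ± 0.08 and Zfp42 (Rex1) at -1.56 ± 0.06. Formative and primed epiblast genes fell in 15 of 18 members and rose in 2 (adjusted p = 2.2e-05), among them the Nodal antagonist genes Lefty1 at -2.84 ± 0.1 and Lefty2 at -2.61 ± 0.07. In the same samples fibroblast feeder markers rose in 20 of 21 members, with a median of 1.18 (adjusted p = 8.9e-09), including Lox at 2.03 ± 0.09, Fbln2 at 1.58 ± 0.07 and the collagen gene Col1a1 at 1.56 ± 0.07. DNA methylation and demethylation enzymes fell in 11 of 16 members and rose in 3 (adjusted p = 0.0093, and adjusted p = 0.093 with an estimated correlation), with the dioxygenase gene Tet1 at -2.28 ± 0.12. Germline genes fell in 12 of 14 members and rose in 1 (adjusted p = 0.013, and adjusted p = 0.093 with an estimated correlation), with Tex19.1 at -1.62 ± 0.07. Primitive endoderm genes rose in 11 of 18 and fell in 3 (adjusted p = 0.0072, and adjusted p = 0.052 with an estimated correlation). Adjusted over the list alone, these 6 lists gave the same counts.

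Cell cycle genes fell in 28 of 30 members and rose in 2 at 10 nM (adjusted p = 3.9e-09), with the replication helicase genes Mcm5 at -1.81 ± 0.05 and Mcm6 at -1.76 ± 0.04. Cholesterol synthesis and SREBP2 target genes fell in 23 of 24 (adjusted p = 9.6e-08), with Idi1 at -2.53 ± 0.1 and the sterol sensor partner Insig1 at -2.39 ± 0.06. HIF and hypoxia genes rose in 14 of 20 and fell in 3 (adjusted p = 0.0012). Adm was at 2.17 ± 0.09, the collagen prolyl hydroxylase gene P4ha1 at 1.52 ± 0.04 and Vegfa at 1.49 ± 0.05, while Pdk1 was at -1.24 ± 0.05. ATF4 and integrated stress response genes rose in 34 of 39 and fell in 4 (adjusted p = 3.8e-07, and adjusted p = 0.093 with an estimated correlation), with Ddit3 at 2.19 ± 0.07 and Gdf15 at 1.93 ± 0.1. Autophagy and lysosome genes rose in 21 of 27 and fell in 5 (adjusted p = 1.4e-04, and adjusted p = 0.11 with an estimated correlation). Of the 21 p53 response genes 12 rose and 3 fell (adjusted p = 0.0073, and adjusted p = 0.23 with an estimated correlation), with Cdkn1a at 263 ± 18.3 against 115 ± 2.89 FPKM. Adjusted over the list alone, these 6 lists gave the same counts, and the fibroblast markers rose in the same samples (Col1a1 at 2.95 times the control mean).

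Nuclear ATP synthase genes fell in 13 of 18 members and rose in 1 at 10 nM, also adjusted over the list alone (adjusted p = 0.029, and adjusted p = 0.76 with an estimated correlation). The call was lost without control replicate 3 (median -0.41, adjusted p = 0.058) and without replicate 1 of 10 nM, the library that stood apart by gene length (median -0.33, adjusted p = 0.062, range 0.014 to 0.76 over 9 alternatives). Glycolysis genes were split, 8 of 23 higher and 9 lower, also adjusted over the list alone (adjusted p = 0.87). Its median was -0.01 and its mean -0.04, while the test pointed higher. Eno2 rose by 1.9 ± 0.06 and the pyruvate dehydrogenase kinase gene Pdk1 fell by 1.24 ± 0.05. Ldha was at 378 ± 21.2 against 381 ± 20.4 FPKM in the controls (adjusted p = 0.87, and 0.0025 under quantile normalization, range 0.0025 to 1 over 13 alternatives). Hk2 changed by -0.51 ± 0.06. Slc2a1 was at 0.14 ± 0.05 (adjusted p = 0.019), and its call was lost without control replicates 1 (0.11, adjusted p = 0.081) or 2 (0.12, adjusted p = 0.065) and without 10 nM replicates 2 (0.12, adjusted p = 0.059) or 3 (0.12, adjusted p = 0.063). It was also lost under quantile normalization and in a fit of only the groups compared, within a range of 4e-04 to 0.11 over 13 alternatives.

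The unfolded protein response list, 14 of 28 higher and 5 lower, was not called at 10 nM (adjusted p = 0.066, and 0.033 under median ratio scaling, range 0.033 to 0.24 over 9 alternatives), though Herpud1 rose by 1.18 ± 0.07. Hspa5 was at 222 ± 17.6 FPKM (adjusted p = 0.48). Of 75 cytosolic ribosomal protein genes 26 fell and 1 rose (23 and 0 adjusted over the list alone), which was not called as a list (adjusted p = 0.23). It was called without replicate 2 (median -0.2, adjusted p = 0.039) or replicate 3 (adjusted p = 0.04) of 10 nM, within a range of 0.039 to 0.94 over 9 alternatives. Both of those fits keep replicate 1, the library that stood apart by gene length. Counts higher and lower were 5 and 18 of 61 respiratory complex genes (3 and 13 adjusted over the list alone), 4 and 9 of 24 TCA cycle genes, 4 and 5 of 12 mitochondrially encoded mRNAs and 3 and 10 of 16 mitochondrial chaperones. The prohibitin gene Phb, in the last group, fell by 1.48 ± 0.08. They were 10 and 8 of 24 NRF2 genes, 13 and 8 of 33 hexosamine and N-glycan genes (13 and 7 adjusted over the list alone), 3 and 4 of 9 mesoderm genes, 6 and 7 of 13 neuroectoderm genes and 7 and 5 of 14 trophectoderm genes. None of these lists was called, and except where given the counts were the same adjusted over the list alone. The hexosamine list had a median of 0.06 and a mean of -0.02.

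**Figure D2:**
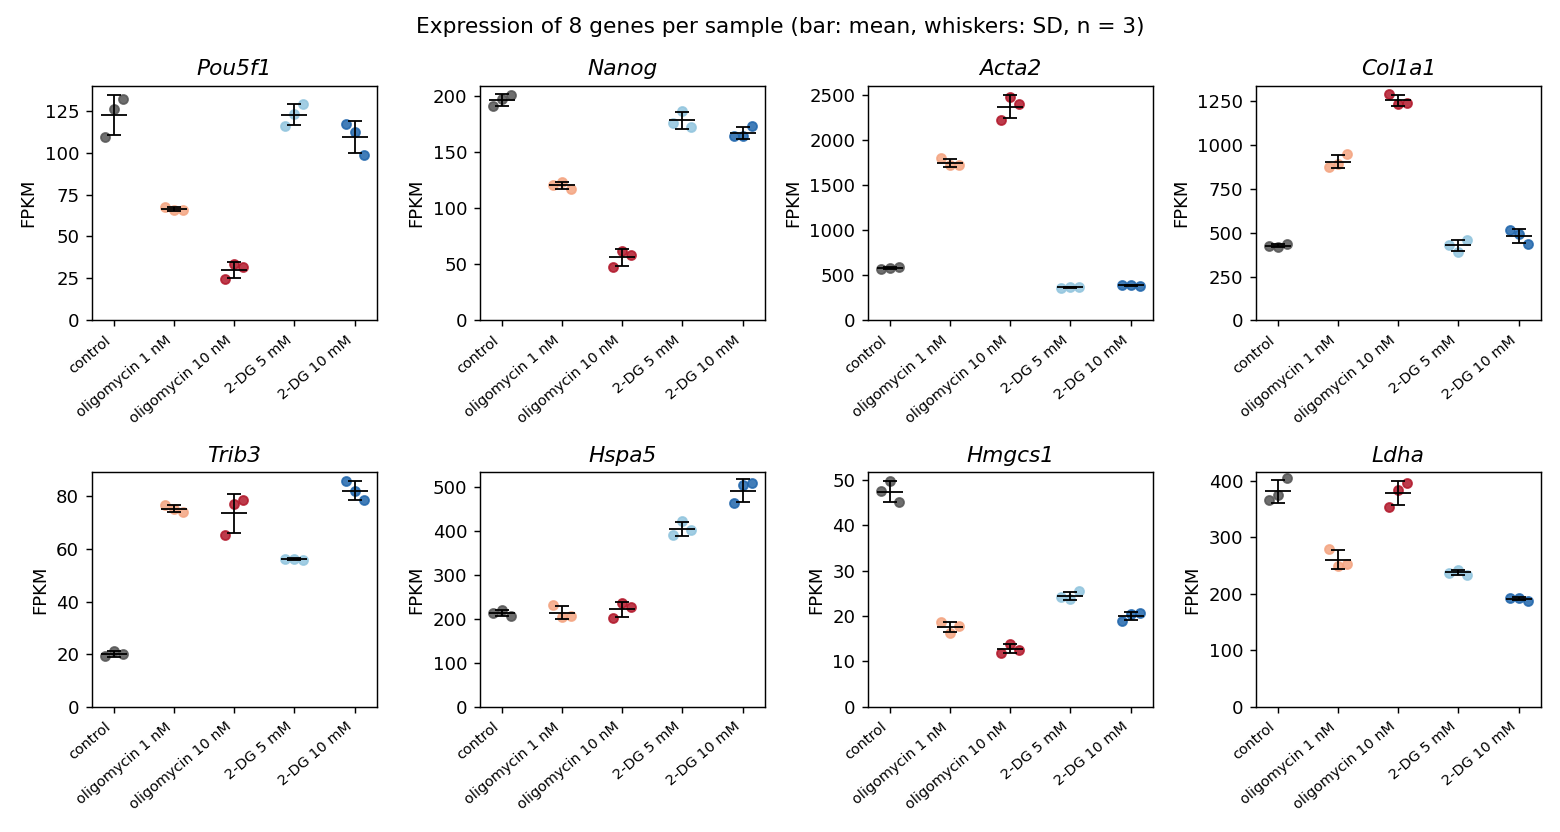
FPKM of 8 genes in each group, with 1 point per sample, the mean as a bar and the SD as whiskers (n = 3). Pou5f1 and Nanog are lowest and Acta2 and Col1a1 highest with 10 nM oligomycin, while Hspa5 is highest with 10 mM 2-DG (491 ± 25.5 FPKM).

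At 5 mM, 2-DG raised genes of the integrated stress response and of the endoplasmic reticulum unfolded protein response and lowered genes of sterol synthesis. Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547) rose from 213 ± 6.36 to 404 ± 15.9 FPKM (SD, n = 3), and Herpud1, a gene of protein degradation at the endoplasmic reticulum, from 11.8 ± 0.759 to 33.4 ± 1.21 FPKM. Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032) rose from 20.2 ± 1.03 to 56.1 ± 0.214 FPKM, and the secreted pattern recognition protein gene Ptx3 from 4.39 ± 0.498 to 21.4 ± 1.21 FPKM. The largest fall was that of the chemokine gene Pf4, from 11.5 ± 0.51 to 0.938 ± 0.199 FPKM. Pou5f1 was at 123 ± 6.4 against 122 ± 11.6 FPKM in the controls (adjusted p = 0.94). In total 4686 genes passed the test, 1990 higher and 2696 lower, and 45 rose and 79 fell at least 2-fold.

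ATF4 and integrated stress response genes rose in 36 of 39 members and fell in 0 at 5 mM (37 and 0 adjusted over the list alone, adjusted p = 1.2e-24), with Atf5 at 1.7 ± 0.09 and the amino acid transporter gene Slc7a1 at 1.1 ± 0.12. Unfolded protein response genes rose in 23 of 28 and fell in 0 (adjusted p = 4.9e-16), with Pdia4 at 0.98 ± 0.06 and Dnajc3 at 0.89 ± 0.06. Cholesterol synthesis and SREBP2 target genes fell in 22 of 24 (adjusted p = 1.6e-14), with the reductase gene Dhcr7 at -1.39 ± 0.07 and Insig1 at -1.16 ± 0.06. The last 2 lists gave the same counts adjusted over the list alone. Germline genes fell in 13 of 14 (14 adjusted over the list alone, adjusted p = 3.1e-06), with the meiosis gene Stra8 at -1.28 ± 0.13. Mesoderm and primitive streak genes fell in 5 of 9 (6 adjusted over the list alone, adjusted p = 0.0013), with Cdx1 at -1.33 ± 0.1.

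Several more lists were called at 5 mM with the preset correlation and lost with an estimated one. Glycolysis genes fell in 14 of 23 and rose in 3 (15 and 4 adjusted over the list alone, adjusted p = 1.8e-04, and adjusted p = 0.091 with an estimated correlation), with Ldha at -0.67 ± 0.06, Slc2a1 at -0.69 ± 0.05, Hk2 at -0.31 ± 0.06 and the lactate exporter gene Slc16a3 at -0.87 ± 0.08. Naive pluripotency genes rose in 13 of 24 and fell in 4 (14 and 4 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.23 with an estimated correlation), with Klf2 at 0.98 ± 0.14, Nr0b1 at 0.95 ± 0.06 and Tdgf1 at -1.07 ± 0.06. Formative and primed epiblast genes fell in 11 of 18 and rose in 4 (12 and 4 adjusted over the list alone, adjusted p = 0.005, and adjusted p = 0.091 with an estimated correlation), with Pou3f1 at -1.18 ± 0.06 and Otx2 at 1.19 ± 0.09. The p53 response genes fell in 12 of 21 and rose in 1 (adjusted p = 0.0013, and adjusted p = 0.17 with an estimated correlation). HIF and hypoxia genes fell in 10 of 20 and rose in 2 (adjusted p = 0.016, and adjusted p = 0.097 with an estimated correlation). Cell cycle genes fell in 9 of 30 and rose in 1 (adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation). Autophagy and lysosome genes rose in 15 of 27 and fell in 2 (adjusted p = 3e-04, and adjusted p = 0.16 with an estimated correlation). These last 4 lists gave the same counts adjusted over the list alone.

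Fibroblast feeder markers were 3 of 21 higher and 5 lower at 5 mM, also adjusted over the list alone, with a median of 0.02 (adjusted p = 0.93). Mitochondrial lists held few called genes, 0 higher and 3 lower of 61 respiratory complex genes (0 and 0 adjusted over the list alone), 1 and 1 of 18 ATP synthase genes (1 and 0), and 3 and 0 of 12 mitochondrially encoded mRNAs (1 and 0). Both nuclear lists had a median of -0.02, with the test pointing higher. The other lists not called were primitive endoderm (6 higher and 4 lower of 18, 7 and 4 adjusted over the list alone), trophectoderm (3 and 7 of 14, 4 and 8), neuroectoderm (4 and 4 of 13, the same), TCA cycle (4 and 7 of 24, 6 and 7) and mitochondrial chaperones (2 and 2 of 16, 2 and 1). The same held for NRF2 genes (5 and 2 of 24, the same), hexosamine and N-glycan genes (10 and 6 of 33, 11 and 6), DNA methylation enzymes (4 and 4 of 16, the same) and cytosolic ribosomal proteins (2 and 0 of 75, 0 and 0). The neuroectoderm (median -0.11, mean -0.02), TCA cycle (-0.01 and -0.02) and DNA methylation lists (0.05 and -0.06) had tests pointing higher. Pmm2, which makes mannose-1-phosphate for N-glycans, rose by 0.86 ± 0.08.

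With 10 mM 2-DG, Hspa5, Trib3 and Atf5 stood higher and Ldha and Slc2a1 lower than in the controls. Hspa5 reached 491 ± 25.5 FPKM (SD, n = 3), 2.3 times the control mean, Trib3 reached 82.1 ± 3.47 FPKM, and Atf5 (ENSMUSG00000038539, chromosome 7, 44812256 to 44816658) rose from 26.8 ± 3.98 to 133 ± 5.05 FPKM. Ldha (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627) fell from 381 ± 20.4 to 191 ± 2.92 FPKM and Slc2a1 from 123 ± 6.2 to 67.5 ± 1.35 FPKM. The imprinted gene Phlda2 fell from 48.5 ± 4.39 to 5.93 ± 0.551 FPKM and Pf4 to 0.624 ± 0.091 FPKM. In total 6401 genes passed the test, 2845 higher and 3556 lower, and 107 rose and 171 fell at least 2-fold.

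ATF4 and integrated stress response genes rose in 37 of 39 members (38 adjusted over the list alone, adjusted p = 5.2e-24) at 10 mM, with the secreted glycoprotein gene Stc2 at 1.79 ± 0.07 and Ddit3 at 1.65 ± 0.07. Unfolded protein response genes rose in 24 of 28 (26 adjusted over the list alone, adjusted p = 7.1e-16), with Herpud1 at 1.82 ± 0.07, Pdia4 at 1.35 ± 0.06 and Dnajb9 at 1.2 ± 0.09. In both lists 0 members fell. Cholesterol synthesis and SREBP2 target genes fell in 23 of 24, also adjusted over the list alone (adjusted p = 6.3e-15), with Dhcr7 at -1.77 ± 0.07 and Insig1 at -1.67 ± 0.06. Formative and primed epiblast genes fell in 12 of 18 and rose in 3 (adjusted p = 3.5e-04), with Tcf15 at -2.04 ± 0.16, Pou3f1 at -1.78 ± 0.06 and Dnmt3b at -1.57 ± 0.05. Germline genes fell in 10 of 14 (adjusted p = 4e-04), with Stra8 at -1.35 ± 0.13 and the synaptonemal complex gene Sycp3 at -0.96 ± 0.13. Both had the same counts adjusted over the list alone.

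Cell cycle genes fell in 22 of 30 and rose in 1 at 10 mM (25 and 1 adjusted over the list alone, adjusted p = 8.4e-06, and adjusted p = 0.068 with an estimated correlation), with Ccne1 at -1.11 ± 0.06. Glycolysis genes fell in 17 of 23 and rose in 2 (17 and 3 adjusted over the list alone, adjusted p = 1.6e-05, and adjusted p = 0.055 with an estimated correlation), with Pdk1 at -1.25 ± 0.05, Slc16a3 at -1.23 ± 0.08 and Hk2 at -0.45 ± 0.06. Autophagy and lysosome genes rose in 17 of 27 and fell in 3, also adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.079 with an estimated correlation), with the protease gene Ctsa at 0.8 ± 0.04. Mesoderm and primitive streak genes fell in 6 of 9 (7 adjusted over the list alone, adjusted p = 0.0049, and adjusted p = 0.055 with an estimated correlation). The naive list was not called, with 12 of 24 higher and 6 lower (12 and 7 adjusted over the list alone, adjusted p = 0.056). It was called without control replicate 3 (median 0.26, adjusted p = 0.033) or 10 mM replicate 1 (median 0.27, adjusted p = 0.048), within a range of 0.033 to 0.51 over 9 alternatives. Pou5f1 was at 109 ± 9.71 FPKM (adjusted p = 0.22) and Sox2 at 170 ± 11.5 FPKM (adjusted p = 0.96). Nanog was at -0.23 ± 0.07 (adjusted p = 0.021), a call lost without control replicates 2 (-0.23, adjusted p = 0.055) or 3 (-0.21, adjusted p = 0.063) and without 10 mM replicates 1 or 2 (both -0.22, adjusted p = 0.063), within a range of 0.0024 to 0.063 over 13 alternatives.

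Fibroblast feeder markers were 6 of 21 higher and 4 lower at 10 mM, also adjusted over the list alone, with a median of 0.17 (adjusted p = 0.17), and Acta2 was at 391 ± 7.27 against 577 ± 10.3 FPKM. The p53 list had 5 of 21 higher and 9 lower and the HIF list 5 of 20 higher and 10 lower, again the same adjusted over the list alone, and neither was called (adjusted p = 0.39 and 0.17). Primitive endoderm genes were 11 of 18 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.056, called without control replicate 1 at median 0.29 and adjusted p = 0.022, or control replicate 2 at median 0.28 and adjusted p = 0.023, range 0.022 to 0.13 over 9 alternatives). Sox7, an endoderm transcription factor gene, rose by 1.31 ± 0.11. Trophectoderm genes were 4 of 14 higher and 8 lower (4 and 9 adjusted over the list alone, adjusted p = 0.079, 0.05 without control replicate 2, range 0.05 to 0.21), with the keratin gene Krt8 at -1.02 ± 0.07. The other lists not called held 6 higher and 6 lower of 13 neuroectoderm genes, 4 and 8 of 24 TCA cycle genes, 2 and 7 of 16 mitochondrial chaperones, 4 and 1 of 12 mitochondrially encoded mRNAs, 7 and 5 of 24 NRF2 genes and 3 and 5 of 16 DNA methylation enzymes. These 6 were the same adjusted over the list alone, and the DNA methylation median was 0.06 with a mean of -0.17 and a test pointing lower. Respiratory complex genes were 1 higher and 10 lower of 61 (0 and 5 adjusted over the list alone), ATP synthase genes 1 and 3 of 18 (the same), hexosamine and N-glycan genes 14 and 8 of 33 (14 and 9) and ribosomal protein genes 2 and 1 of 75 (0 and 0).

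**Figure D3:**
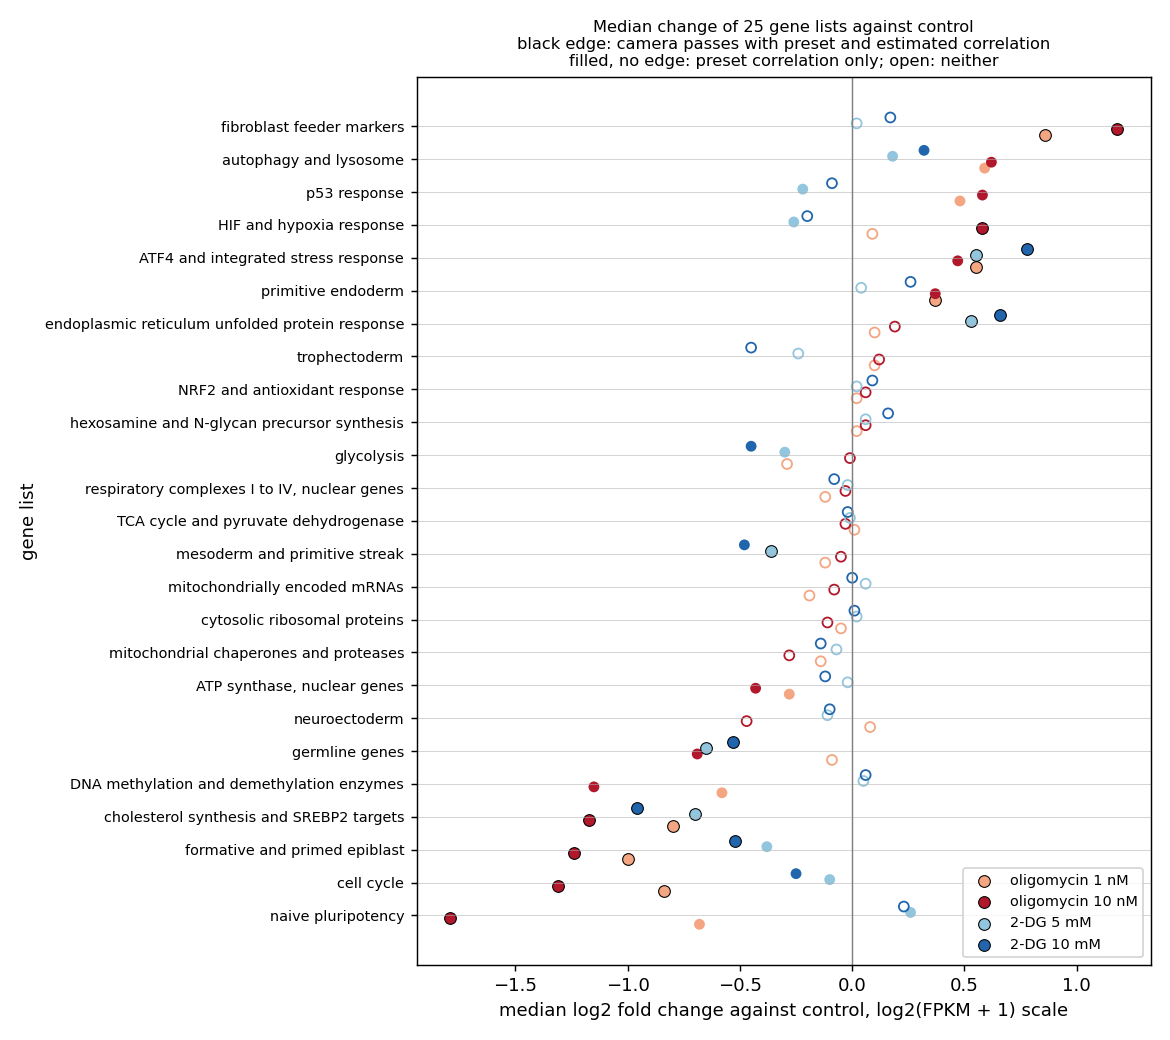
Median log2 change against control of 25 gene lists, with 1 point per list and treatment, ordered by the median at 10 nM oligomycin. Naive pluripotency lies at -1.79 with 10 nM oligomycin and 0.23 with 10 mM 2-DG, while cholesterol genes lie below 0 in all 4 treatments.

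Between the doses of oligomycin, the naive pluripotency genes fell further at 10 nM, 24 of 24, with a median of -1.07 (adjusted p = 1.5e-16). Dppa3 was at -1.67 ± 0.14 (SE, n = 3 per group), Esrrb at -1.52 ± 0.04 and Pou5f1 at -1.13 ± 0.1, and Alpl, the alkaline phosphatase gene used as a stem cell marker, fell from 20.5 ± 1.43 to 5.43 ± 0.809 FPKM. HIF and hypoxia genes rose in 16 of 20 and fell in 1 (adjusted p = 6.7e-07), with Fam162a at 1.17 ± 0.14 and the mitophagy receptor gene Bnip3 at 0.85 ± 0.08. In total 6161 genes passed, 2489 higher and 3672 lower, with 9 rising and 122 falling at least 2-fold, and 6650 passed without replicate 1 of 10 nM. The share higher was 40.4%, and 52.4% under quantile normalization.

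Fibroblast feeder markers rose in 15 of 21 between the oligomycin doses (17 adjusted over the list alone, adjusted p = 3.5e-07). Cell cycle genes fell in 24 of 30 and rose in 2 (26 and 2 adjusted over the list alone, adjusted p = 1.9e-08). Germline genes fell in 12 of 14 (13 adjusted over the list alone, adjusted p = 7.8e-05). Cholesterol genes fell in 17 of 24 (adjusted p = 7.8e-05) and DNA methylation enzymes in 10 of 16 with 1 higher (adjusted p = 0.0014). Glycolysis genes rose in 12 of 23 and fell in 5 (adjusted p = 0.02, and adjusted p = 0.29 with an estimated correlation), with Slc16a3 at 0.96 ± 0.08, Ldha at 0.54 ± 0.06 and Slc2a1 at 0.45 ± 0.05. The naive, HIF, cholesterol, DNA methylation and glycolysis counts were the same adjusted over the list alone. ATF4 genes were 6 of 39 higher and 13 lower, also adjusted over the list alone (adjusted p = 0.5).

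A few calls between the oligomycin doses rested on single libraries. Formative and primed epiblast genes fell in 10 of 18 and rose in 2, also adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.16 with an estimated correlation), and the call was lost without 10 nM replicate 1 (-0.26, adjusted p = 0.056, range 0.02 to 0.16). Primitive endoderm genes rose in 8 of 18 and fell in 2, also adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.12 with an estimated correlation). That call was lost under median ratio scaling (0.2, adjusted p = 0.058) and without replicate 1 of 1 nM (0.16, adjusted p = 0.052) or of 10 nM (0.11, adjusted p = 0.094, range 0.02 to 0.12). NRF2 genes rose in 9 of 24 and fell in 4 (11 and 4 adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.72 with an estimated correlation), lost without 10 nM replicate 2 (0.07, adjusted p = 0.1) or 3 (0.09, adjusted p = 0.053, range 0.003 to 0.72). Nqo1, a quinone reductase gene of that list, rose by 0.61 ± 0.06.

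Between the doses of 2-DG, stress genes rose and sterol genes fell further at 10 mM. ATF4 and integrated stress response genes rose in 16 of 39 and fell in 0 (29 and 0 adjusted over the list alone, adjusted p = 2.6e-16), with Ddit3 at 0.62 ± 0.07 (SE, n = 3 per group), Atf5 at 0.59 ± 0.09 and Trib3 at 0.54 ± 0.06. Unfolded protein response genes rose in 10 of 28 (13 adjusted over the list alone, adjusted p = 1.8e-10), with Dnajc3 at 0.43 ± 0.06. Cholesterol genes fell in 11 of 24 (17 adjusted over the list alone, adjusted p = 1.2e-13), with Insig1 at -0.51 ± 0.06. Formative and primed epiblast genes fell in 7 of 18 (10 adjusted over the list alone, adjusted p = 3.2e-08), with Dnmt3b at -0.7 ± 0.05. In total 779 genes passed, 453 higher and 326 lower, with 0 rising and 1 falling at least 2-fold, which was Phlda2 at -1.16 ± 0.11. Leaving out any 1 of the 6 samples gave 273 (without 10 mM replicate 2) to 468 genes (without 10 mM replicate 1).

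Cell cycle genes fell in 7 of 30 between the 2-DG doses (14 adjusted over the list alone, adjusted p = 8.1e-10). Glycolysis genes fell in 4 of 23 (11 adjusted over the list alone, adjusted p = 1.3e-06), with Ldha at -0.32 ± 0.06. Autophagy genes rose in 8 of 27 (11 and 1 lower adjusted over the list alone, adjusted p = 1.4e-05, and adjusted p = 0.092 with an estimated correlation). The p53 genes rose in 6 of 21 (11 adjusted over the list alone, adjusted p = 2.3e-04, and adjusted p = 0.092 with an estimated correlation). Fibroblast feeder markers rose in 2 of 21 (3 adjusted over the list alone, adjusted p = 9.9e-04, and adjusted p = 0.092 with an estimated correlation), of which Lox was at 0.48 ± 0.09. Primitive endoderm genes rose in 2 of 18 and fell in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.012, and 0.079 with an estimated correlation). Trophectoderm genes fell in 4 of 14 (5 and 1 higher adjusted over the list alone, adjusted p = 0.016, and 0.092 with an estimated correlation). DNA methylation enzymes fell in 5 of 16 and rose in 1, also adjusted over the list alone (adjusted p = 0.0088, and 0.092 with an estimated correlation). Of 24 naive genes 1 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.062, 0.046 under median ratio scaling and 0.034 without 5 mM replicate 3, range 0.034 to 0.62 over 9 alternatives).

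The direct comparison of 10 mM 2-DG with 10 nM oligomycin set the high doses of both inhibitors side by side. All 24 naive pluripotency genes were higher with 2-DG (adjusted p = 1e-11), with a median of 1.77, and Dppa3 was at 61.7 ± 6.94 against 6.09 ± 1.18 FPKM (SD, n = 3). Calcoco2, an autophagy receptor gene, was at 40.2 ± 0.967 against 1.33 ± 0.236 FPKM. The smooth muscle actin genes were lower with 2-DG, Actg2 at 32.3 ± 0.531 against 248 ± 17.2 FPKM and Acta2 at -2.6 ± 0.05 (SE). Hspa5 was 2.21 times as high with 2-DG, and Cdkn1a 0.46 times as high. In total 9411 genes passed, 5003 higher and 4408 lower with 2-DG, with 823 and 617 at least 2-fold, and 9495 passed without replicate 1 of 10 nM oligomycin.

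Cell cycle genes were higher with 10 mM 2-DG than with 10 nM oligomycin in 28 of 30 and lower in 2 (adjusted p = 1.1e-08), with Mcm5 at 1.57 ± 0.05. Unfolded protein response genes were higher in 20 of 28 and lower in 2 (adjusted p = 2.4e-04). DNA methylation enzymes were higher in 12 of 16 and lower in 1 (adjusted p = 0.002, and adjusted p = 0.067 with an estimated correlation), with Tet1 at 1.87 ± 0.12. Fibroblast feeder markers were lower in 19 of 21 (adjusted p = 1.5e-08). HIF genes were lower in 17 of 20 and higher in 1 (adjusted p = 6.7e-06), with Adm at -2.18 ± 0.09. The p53 genes were lower in 17 of 21 and higher in 2 (adjusted p = 1.7e-04, and adjusted p = 0.11 with an estimated correlation). Glycolysis genes were lower in 14 of 23 and higher in 4 (adjusted p = 0.0094, and adjusted p = 0.2 with an estimated correlation), with Slc16a3 at -1.92 ± 0.08 and Gapdh at 1.18 ± 0.12. ATF4 genes were 20 of 39 higher and 9 lower (adjusted p = 0.082). Cholesterol genes were 13 of 24 higher and 5 lower (adjusted p = 0.23), and neither list was called. Primitive endoderm genes were lower in 11 of 18 and higher in 3 (adjusted p = 0.022, and adjusted p = 0.095 with an estimated correlation). Autophagy and lysosome genes were lower in 16 of 27 and higher in 7 (adjusted p = 0.022, and adjusted p = 0.33 with an estimated correlation). Adjusted over the list alone, all lists of this comparison named so far gave the same counts. Formative genes were higher in 11 of 18 and lower in 4 (11 and 5 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.16 with an estimated correlation).

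Genes called with both high doses were counted to see how far the inhibitors changed the same genes. Both raised 1844 genes and both lowered 2375, where independent calls would give 969 and 1484, and 1107 genes went opposite ways, where independent calls would give 2398. Of the 4219 genes that changed in the same direction, Trib3, Ptx3 and Atf5 rose with both, and Phlda2, Tcf15 and Insig1 fell with both. Both comparisons used the same 3 control samples, so their errors were shared. In 100 simulations with the shared controls and no treatment effect, at most 2 genes were called in the same direction in both. With no effect to call, such a small count is fixed in advance and is no chance level for the 4219 genes. The covariance of the log2 changes across genes was 0.118, against 0.00664 from the shared controls alone in the simulations (difference 0.112), and Pearson's r was 0.44 across 13284 genes, which are not independent replicates. Shared controls alone gave r of 0.5 in the simulations, where all variation was error and no treatment effect entered. That value is therefore no baseline for the r here, and r decides nothing about a shared response. Part of any excess over independence comes from the shared controls, and 3 controls are too few to split into separate sets. By dose, 3589 genes rose and 4146 fell at both oligomycin doses, where independent calls would give 1348 and 1840, and 64 went opposite ways. For the 2-DG doses 1759 rose and 2376 fell at both, where independent calls would give 426 and 722, and 2 went opposite ways. These pairs share the controls too, and the simulations gave at most 1 and 0 genes in the same direction, again with no treatment effect to call.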

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

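Both tests of cell share given here were chosen after the results were seen. Before the data were examined, the comparison of 10 mM 2-DG with 10 nM oligomycin had been fixed, and in 4 gene lists the medians of the high doses against control had opposite signs while the direct comparison passed the test. The naive pluripotency list stood at -1.79 with oligomycin and 0.23 with 2-DG, a median difference of 1.77 (adjusted p = 1e-11, and 0.039 with an estimated correlation). HIF and hypoxia genes stood at 0.58 and -0.2, a median difference of -0.84 (adjusted p = 6.7e-06, and 0.025 with an estimated correlation). The p53 response genes stood at 0.58 and -0.09, a median difference of -0.77 (adjusted p = 1.7e-04, and 0.11 with an estimated correlation). DNA methylation and demethylation enzymes stood at -1.15 and 0.06, a median difference of 1.11 (adjusted p = 0.002, and 0.067 with an estimated correlation). None of the 4 was called with 10 mM 2-DG against control (adjusted p = 0.056, 0.17, 0.39 and 0.68 in this order), and the DNA methylation list had a mean of -0.17 there, the direction seen with oligomycin. The 13 genes restricted to stem cells, a list written after the data were seen, had a median of -0.23 there (7 lower and 1 higher). That too was the direction seen with oligomycin. Fibroblast feeder markers were lower with 2-DG in 19 of 21 members of the direct comparison. A change in cell share was not tested for the HIF, p53 and DNA methylation lists.

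In oligomycin the pluripotency genes fell while fibroblast feeder markers rose, so a smaller share of stem cells in the RNA was weighed. A dilution alone would lower all genes restricted to stem cells by 1 factor. That holds if the stem cells were alike and no other cell expressed these genes, which was not tested. Of the 13 genes 6 lay more than 3 SE from their median of -1.97, from L1td1 at -2.65 to Fgf4 at -1.46 (both named after their values were seen). Only under that condition does the spread argue against dilution as the whole cause. A larger share of fibroblasts as part of the cause cannot be told apart from changes within the cells. A mixture of 2 fixed profiles was solved at 10 nM, with a stem cell share of the RNA of 65.7% in the controls. It predicted a fibroblast median of 0.88 at 1 nM where 0.92 was observed (standard error over members 0.06, which are not independent). These medians are log2 ratios of mean FPKM without the added 1. They cover the 17 markers with at least 5 FPKM in the controls, whose median with the added 1 was 0.9. Of the 17 markers, 9 lay more than 3 SE from their median at 10 nM and 5 at 1 nM. A fixed profile would raise them all by 1 factor if no other cell expressed them, which was not tested. The match of medians therefore does not show that a mixture holds. Y-linked genes changed relative to their X-linked partners by a median of -0.12, from Eif2s3y at -0.28 to Uty at 0.24, which did not separate the cases, while Xist rose from 3.33 ± 1.14 to 9.25 ± 2.71 FPKM (log2 change 1.24 ± 0.26, adjusted p = 6.2e-04, all chosen after their values were seen). A response of the stem cells themselves to the drug, including a turn to fibroblast-like expression, may account for the rest and was not tested.

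All 17 fibroblast markers with at least 5 FPKM in the controls rose at both oligomycin doses, from 0.78 for Col3a1 to 2.03 for Acta2 at 10 nM. With 10 mM 2-DG they ranged from -0.56 for Acta2 to 0.9 for Lox. The most abundant of those named, Acta2 and Col1a1, stood at 577 ± 10.3 and 426 FPKM in the controls, and the labels name neither feeders nor a sort. All 13 genes restricted to stem cells fell at both doses, with a median of -0.82 at 1 nM, and 4 of 5 epithelial genes of stem cells fell with 1 higher, with medians of -0.33 and -1.06. In 10 mM 2-DG the 13 genes had a median of -0.23, with 7 lower and 1 higher (8 and 1 adjusted over the list alone), and the 5 epithelial genes -0.52, with 4 lower and 0 higher, and the other counts here were the same adjusted over the list alone.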

How the results depend on the processing

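Leaving out single samples for the gene lists was chosen after the data had been seen, and all other alternatives and the splits of the samples were fixed earlier. The 7 counts of genes past the test and the count shared by both high doses stayed within 1.5 times their reported values under a pseudocount of 0.1, both other filters, both scalings, the fit of only the groups compared and the replicate block. The ranges were 6004 to 8712 for 1 nM oligomycin, 6890 to 11562 for 10 nM, 3209 to 4854 for 5 mM 2-DG, 4420 to 6591 for 10 mM, 4726 to 6389 between oligomycin doses, 535 to 907 between 2-DG doses, 6553 to 10556 between the inhibitors and 2999 to 4270 for the shared genes. The lowest came from the filter at 5 FPKM, which tests fewer genes, except between 2-DG doses, where it came from no filter. Leaving out 1 sample moved 6 of 51 counts, all for 10 mM against 5 mM 2-DG, which gave 273 to 468 genes in place of 779, with fewer samples in the test. Among genes called against control, the share higher was 47.3% (44.9% to 50.6% over all settings) for 1 nM oligomycin and 44.9% (43.3% to 50.4%) for 10 nM. For 2-DG it was 42.5% (40% to 50.4%) at 5 mM and 44.4% (42.4% to 50.8%) at 10 mM. The larger number of falls thus did not hold under every setting. The labels do not say that replicate numbers pair the samples, and in no comparison did all 3 same-numbered pairs deviate together with r over 0.1, though 2 did for 10 nM oligomycin (0.37, 0.02 and 0.23). The block gave 10023 genes in place of 10067 for oligomycin 10 nM against control. Median ratio scaling shifted the median of all genes by at most 0.073 (log2). The count tests named in advance were conditional on raw counts and were not run.

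Of 175 list results, 41 lost their call with an estimated correlation and 134 did not change sides. Median ratio scaling weakened 1 and strengthened 2, the block changed 0, and leaving out samples weakened 13 and strengthened 17 of 1050. Of 781 results for named genes, the largest number weakened by a setting was 40, with no filter, and leaving out samples weakened 253 of 4661. The sign of 1 changed, mt-Co1 for 10 nM against 1 nM oligomycin, which fell by 0.52 and stood at 0 under quantile normalization (adjusted p = 1, range 0.0012 to 1), and the cause was not tested. Between 2-DG doses the ATP synthase list (0 of 18 genes called by limma, adjusted p = 0.03, range 0.014 to 0.65) and the respiratory complexes (1 of 61 called, adjusted p = 0.0088, range 0.001 to 0.65) both had adjusted p = 0.65 with an estimated correlation. The ATP synthase list was also lost without 5 mM replicate 2 (adjusted p = 0.16) or 10 mM replicates 1 (0.064) or 3 (0.065), and respiratory complexes without 5 mM replicate 2 (0.052) or 10 mM replicate 3 (0.053).

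The 6 samples of a comparison can be split into 3 against 3 in 10 ways, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many genes. The real and highest other counts were 8366 and 0 for 1 nM oligomycin, 10067 and 0 for 10 nM, 4686 and 0 for 5 mM 2-DG, 6401 and 0 for 10 mM, 6161 and 39 between oligomycin doses, 779 and 0 between 2-DG doses, and 9411 and 0 between the inhibitors. Of simulated changes of 0.3 (log2), 28% to 42% were recovered, with 200 changed genes among 13284. The adjustment is stricter with so few changed genes than in the real comparisons, which called 779 to 10067 genes. The simulated shares therefore do not tell how many small changes were missed in the data.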

Other observations

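The macrophage and interferon lists and all tests of explanations in this part were chosen after the values were seen, as were the genes of those lists that are named. Most genes of a list typical of macrophages were lower with 2-DG. Of its 20 genes, which were not tested as a set, 14 fell and 1 rose at 5 mM and 13 fell and 1 rose at 10 mM (17 and 1, and 13 and 1, adjusted over the list alone). The complement gene C1qa (ENSMUSG00000036887) fell from 14.6 ± 1.68 to 1.8 ± 0.31 FPKM at 10 mM (SD, n = 3), the chemokine gene Ccl6 from 8.26 ± 0.928 to 0.52 ± 0.128 FPKM, and Lyz2 by 1.4, while Laptm5 rose by 0.79. With oligomycin, 8 rose and 3 fell at 1 nM and 10 rose and 4 fell at 10 nM, the same adjusted over the list alone, among them Cd68 at 0.84 and C1qb at -1.02 at 10 nM.

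Of 20 interferon response genes, which were not tested as a set, 19 rose with 1 nM oligomycin and 16 with 10 nM, and 0 fell. Fibroblast feeder markers rose in the same samples, 19 of 21 at 1 nM and 20 of 21 at 10 nM, and a change in cell share was not tested for the interferon genes. With 2-DG, 18 fell at 5 mM and 13 at 10 mM, and 0 rose, with 1 higher at 10 mM adjusted over the list alone and the other counts the same. Ifit3 (ENSMUSG00000074896), an antiviral gene, stood at 9.13 ± 0.947 FPKM in the controls, 21.4 ± 1.14 with 1 nM oligomycin, 12.3 ± 0.441 with 10 nM, 1.75 ± 0.197 with 5 mM 2-DG and 2.51 ± 0.347 with 10 mM (SD, n = 3). In the direct comparison of the high doses, 19 of 20 interferon genes and 19 of 20 macrophage genes were lower with 2-DG. Between 2-DG doses 9 interferon genes rose toward 10 mM (11 adjusted over the list alone), while 0 macrophage genes changed by the limma test, also adjusted over the list alone.

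The fall of macrophage genes with 2-DG was weighed against a loss of macrophages from the cultures. Loss alone would lower all of them by 1 factor if no other cell in the cultures expressed them, which was not tested. Of the 12 genes with at least 5 FPKM in the controls, 9 lay more than 3 SE from their median of -1.23 at 10 mM, from Pf4 at -2.95 to Laptm5 at 0.79. Only under that condition does the spread argue against loss as the whole cause. Fewer macrophages may account for part of the fall, or for more of it if other cells express these genes. Changes of expression within macrophages were not tested. The labels name no macrophages and no sort that would remove them, and no biological explanation of what remains was tested.

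In all 4 comparisons with control the cholesterol list was called lower and the ATF4 list higher, the latter at 10 nM oligomycin with adjusted p = 0.093 with an estimated correlation and 4 of 39 members lower. All 4 used the same 3 controls, so control libraries that stand apart were weighed as the whole cause. For cholesterol genes this is argued against by the dose comparisons, which use no control and gave medians of -0.37 for oligomycin and -0.28 for 2-DG, both past the test with preset and estimated correlations. For ATF4 genes with 2-DG it is argued against by a median of 0.2 between doses. For ATF4 genes with oligomycin the median between doses was -0.07 (adjusted p = 0.5), which tests only for a further rise with dose and decides nothing about the controls. No label or table used here gives a batch of the control libraries. A response to each inhibitor is 1 biological explanation and may hold as a hypothesis, with no test of the controls for the ATF4 genes in oligomycin. Fibroblast feeder markers also rose with oligomycin, in 19 of 21 members at 1 nM, 20 of 21 at 10 nM and 15 of 21 between the doses. A change in cell share was not tested for the cholesterol and ATF4 genes.

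The 2-cell-like genes, 27 members that mark a rare state of stem cells, lay under the filter. Their summed FPKM was 2.06 ± 0.489 in the controls, 1.61 ± 0.247 with 1 nM oligomycin, 1.61 ± 0.378 with 10 nM, 0.966 ± 0.219 with 5 mM 2-DG and 0.975 ± 0.127 with 10 mM (SD, n = 3), and these sums were not tested.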
